A study of Homo sapiens with 2 samples.

How the data were processed

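RNA of LNCaP cells was measured on 2 Affymetrix Human Gene 1.0 ST arrays, which report on whole transcripts with probes spread over their exons. LNCaP is an established human prostate carcinoma line that responds to androgen. One array held RNA of cells transfected with miR-582-5p and the other RNA of cells transfected with the empty vector, so each group had 1 sample. Total RNA was purified with a commercial kit and the cDNA was labelled with biotin, per the labels' protocols. Whether the transfected cells were single clones or pools, and how long they were cultured, is not given in the sources used here.

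The value table holds the authors' normalized log2 expression values, 1 per probe set and array. The normalization method, its software and the genome build are not given in the sources used here. Values ran from 4.24 to 14.18 over 28869 probe sets, with a median of 6.63 on each array. A second deposited table is the authors' comparison of their array 01 against array 02, given as a log2 fold change and as an absolute fold (a ratio of at least 2). It lists 205 probe sets, all lower, with no p-value. Every one of its log2 values equals the miR-582-5p value minus the empty vector value within 0.001, which fixes its direction and the base of the logarithm. The table's other 4 columns of values per array carry no sample name and were not used.

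Probe sets were named from GEO's platform annotation: 19310 listed 1 gene, 1752 listed several, and 7807 were unnamed here. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCh38.p14, which held 19279 of the 19310. Only probe sets with 1 gene entered the gene table. Probe sets of the same gene were averaged, giving 18377 genes, of which 685 had several probe sets. The reference table gave each gene's chromosome and the order of genes along it, and no coordinates are reported because the files name no build. The 29 gene lists, the size and level rules and the first group of settings given below were fixed before the data were examined. The list members were matched through current symbols and synonyms.

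The measure for each gene is the log2 value of the miR-582-5p array minus that of the empty vector array. With 1 array per group there is no residual spread between samples, so no p-value, standard error or count of significant genes was computed, and size rules stand in their place. A gene was counted when it was at least 2-fold apart and its mean over both arrays was at or above the median gene (a log2 value of 7.48), which left 9189 genes. For each list the median difference of its members among these genes was set against 10000 random lists of the same size, drawn with replacement from genes in the same of 20 bins of mean level. A list is described as standing apart when its median lay under the 2.5 or over the 97.5 percentile of those lists. Random lists hold no co-regulated genes, so the percentile describes these 2 arrays and is not a test of the transfection. Lists with fewer than 5 such genes are given as values only, a limit set after the data were seen.

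The genes named in the text are the 12 highest and the 12 lowest differences among the 9189 genes, PDE4D (the host gene of the miRNA), EFNB2 (known from the study as a candidate target), and up to 4 members of each list at or above the median level: those with the largest differences in the direction of the list's median, with the largest in the other direction where it passed 1.5-fold. Genes named outside this rule are marked as chosen after their values were seen. The steps were tested on simulated independent normal noise, scaled to the interquartile range of the 9189 genes' differences at each level. Such noise holds no co-regulated genes, so it does not show how often lists of such genes stand apart. Of 200 genes changed 3-fold, 198 passed the 2-fold rule, and of 200 changed exactly 2-fold, 98 did, as noise alone decides at the threshold itself. A shift of -0.2 in the S phase list was found in 50 of 50 simulations, and no shift was called apart in 3 of 50. A boundary on a chromosome was placed by least absolute deviation, and set against 1000 shuffles of its gene order, a test added after seeing the data. On the gene order of chromosome 6, a simulated step of 0.3 was placed within 10 genes in 47 of 50 simulations.

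Alternatives were quantile normalization of both arrays, removal of a loess curve of the difference on the mean level (span 0.3), no level filter, a filter at the upper quartile, thresholds of 1.5-fold and 3-fold, the brightest probe set of each gene, and random lists not matched on level. Removal of the median of the 20 genes on each side along the chromosome, and leaving out chromosomes 1, 6 and 9, were added after seeing the data. A planned comparison of genes with and without a miR-582-5p seed site was not run, because 3' UTR sequence was not used here. Arrays carry no read depth; their number limits the precision. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.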

Results

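The expression profile of LNCaP prostate cancer cells transfected with miR-582-5p was compared with that of LNCaP cells carrying the empty vector, to find which transcripts differ when this miRNA is introduced. Each condition was measured on 1 array. No value below therefore has a replicate error, and a difference describes these 2 RNA samples. The arrays correlated with r = 0.988 over 28869 probe sets, a correlation across probe sets, which are not independent replicates. Of the 9189 genes at or above the median level, 92.8% were under 1.5-fold apart, and the central 95% of differences ran from -0.68 to 0.67 on the log2 scale, around a median of -0.03. For 298 genes with several probe sets at or above that level, the difference between the arrays was compared between probe sets. Within a gene, the highest such difference minus the lowest had a median of 0.04, with a 95th percentile of 0.35. That spread covers probe differences only, not the variation between cultures.

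The miRNA itself could not be followed, since no probe set was named MIR582 and the array does not measure mature miRNA. PDE4D, the gene whose intron holds the miR-582 hairpin, was dim on both arrays, at 5.95 with miR-582-5p and 6.05 with the empty vector. EFNB2, which encodes the transmembrane ligand ephrin-B2, was 2.54-fold lower with miR-582-5p, at 7.21 against 8.55 on the log2 scale. That was the 41st lowest of the 9189 differences.

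A total of 89 genes were at least 2-fold higher and 79 at least 2-fold lower in the miR-582-5p cells. The largest measured difference among the genes with a probe set of their own was in PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, at 10.10 against 4.99 on the log2 scale, a ratio of 34.4. The empty vector value lies below that array's lower quartile of 5.21 and is not shown to be above background, so the size of this ratio is uncertain. TMEM45B, a transmembrane protein gene, was 20.5-fold higher, and CNTN5, a neural adhesion molecule of the contactin family, was higher by 4.17 on the log2 scale. RALYL, an RNA-binding protein gene, was 17.5-fold higher and the imprinted gene MEST 11.8-fold higher. The related olfactory receptor genes OR51E2 and OR51E1, known for expression in prostate, were 10.9-fold and 7.58-fold higher. ST8SIA4, a polysialyltransferase, was 10.6-fold higher, the lipid transporter gene ABCA12 9.40-fold and the polymeric immunoglobulin receptor gene PIGR 9.24-fold. BCHE, which encodes butyrylcholinesterase, was 9.23-fold higher and MYBPC1, a myosin-binding protein gene, 9.09-fold.

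In the other direction, CBLN2, a secreted synaptic organiser, was 16.9-fold lower in the miR-582-5p cells (6.80 against 10.88 on the log2 scale). The imprinted, retrotransposon-derived gene PEG10 was 15.5-fold lower and the fucosidase gene FUCA2 14.6-fold lower. The clustered protocadherin genes PCDHB5 and PCDHB2 were 9.65-fold and 5.99-fold lower. PTGFR, the receptor for prostaglandin F, was 7.70-fold lower, while PTGS2 was higher. GNAQ, a G protein alpha subunit, was 7.13-fold lower and RLN1, which encodes relaxin 1, was 6.38-fold lower. Both lie on chromosome 9, whose genes as a group were lower. AADAT, an aminotransferase of the kynurenine pathway, was 5.98-fold lower, GPX8, an endoplasmic reticulum peroxidase, 5.68-fold, PPFIA2 5.30-fold and TMEFF2 4.71-fold. For 13 of these 24 genes, PEG10 and FUCA2 among them, the lower of the values lay below its array's median of 6.63. No detection call was used here, so such a value may be background and the size of the fold is uncertain.

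**Figure D1:**
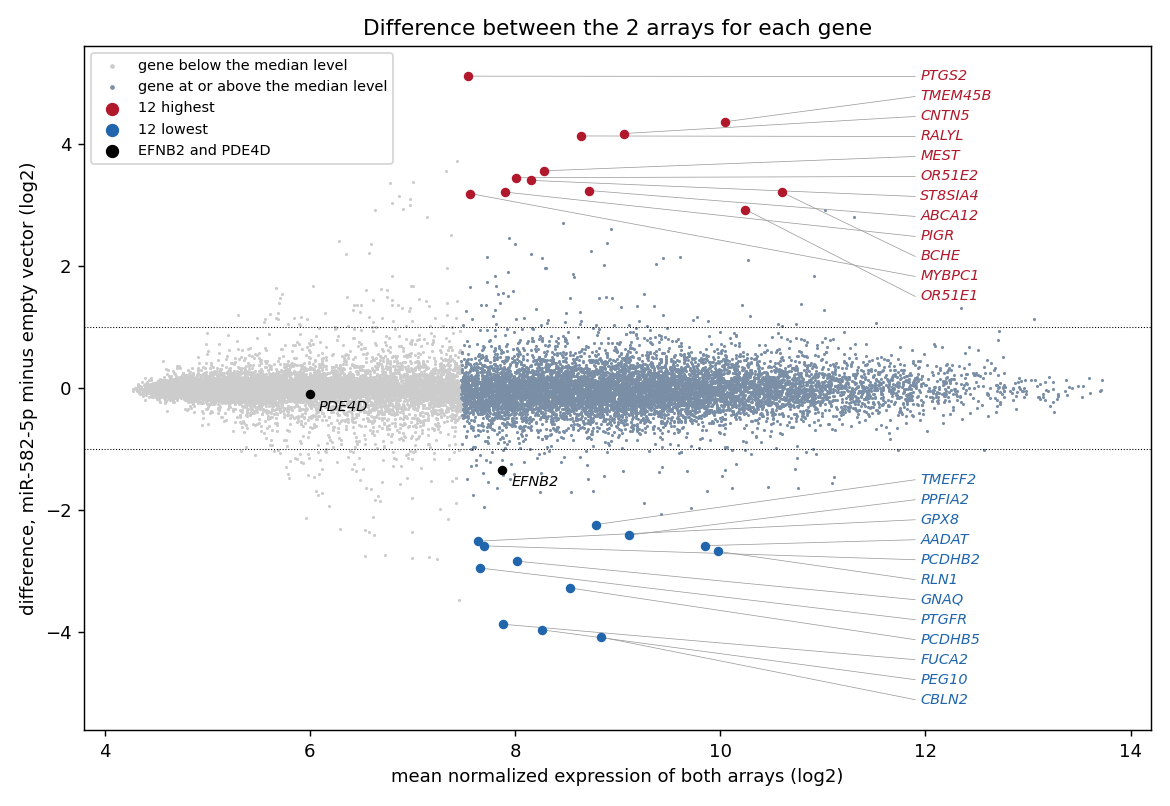
Each point is 1 gene, with the mean normalized expression of both arrays on the x axis (log2) and the difference, miR-582-5p minus empty vector, on the y axis (log2). Dotted lines mark 2-fold; red and blue points are the 12 highest and 12 lowest genes at or above the median level, from PTGS2 at 5.11 to CBLN2 at -4.08, and black points are EFNB2 (-1.34) and PDE4D (-0.10).

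The deposited comparison lists the lower side alone. The authors' deposited table holds 205 probe sets, with absolute folds up to 16.9, and these are exactly the 205 probe sets at least 2-fold lower in the value table. The value table also holds 232 probe sets at least 2-fold higher, which the authors' deposited table does not list.

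Genes of the cell cycle were lower in the miR-582-5p cells. The 38 S phase genes had a median difference of -0.44, a fold of 1.36, and 34 of them were lower. TYMS, thymidylate synthase, was 1.83-fold lower, the DNA polymerase gene POLA1 1.83-fold and the replication helicase gene MCM2 1.77-fold, and WDR76 was 1.51-fold higher. The 52 genes of G2 and M phase had a median of -0.34, with 45 lower, among them HMGB2 at 1.72-fold, the kinetochore gene NDC80 at 1.62-fold, CKAP2L at 1.55-fold and the spindle gene TPX2 at 1.54-fold. Among 22 replication-dependent histone genes, 19 were lower, with a median of -0.30, which was -0.19 with the neighbour median removed. Many of them lie close together on chromosome 6, so the neighbours include other histone genes and their removal takes away part of the list's own difference. H3C10 was 1.75-fold, H2BC21 1.68-fold, H2AC13 1.62-fold and H2BC13 1.60-fold lower, and these near-identical genes can share probe signal. The medians of these 3 lists lay below those of all 10000 matched random lists. No member of the cell cycle lists reached 2-fold. Among 21 p53 target genes, 15 were higher, with a median of 0.13 at the 99.2 percentile. CDKN1A, the p21 cyclin-dependent kinase inhibitor, was 1.85-fold higher, FAS 1.66-fold and POLH 1.44-fold, while the kinase gene PLK2 was 3.21-fold lower. The neighbours of POLH, on chromosome 6, had a median of 0.26. The p53 median lay at the 88.3 percentile once the median of neighbouring genes on the chromosome was removed, and at the 94.2 percentile among genes in the upper quartile of level.

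Markers of luminal prostate cells were lower. The 14 measured at or above the median level had a median of -0.29, at the 0.05 percentile. Of these, 10 were lower, 4 of them at least 2-fold, and 4 were higher. SLC45A3, which encodes prostein, was 3.90-fold lower, AZGP1, zinc-alpha-2-glycoprotein, 3.11-fold, the kallikrein gene KLK2 2.57-fold and the transcription factor gene SPDEF 2.01-fold. KLK3, the gene of prostate-specific antigen, named after its value was seen, differed by -0.39. The broader list of 76 androgen response genes did not stand apart, with a median of -0.06 at the 17.3 percentile. It held large differences in both directions: 8 genes were at least 2-fold lower, including SLC45A3 and AZGP1, which are on both lists, and the TGF-beta regulator PMEPA1 at 2.58-fold, and 4 were at least 2-fold higher, including the secreted phospholipase gene PLA2G2A at 6.99-fold. Without the level filter this list had a median of -0.10, at the 0.70 percentile. Of 7 androgen-repressed genes, BCHE was higher, TMEFF2 and the opioid receptor gene OPRK1 (2.05-fold) were lower, and ST7 was 1.60-fold lower. The median of that list was -0.11 and changed sign with the level filter, to 0.21 with none and 0.52 at the upper quartile.

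Markers of other prostate cell types were mostly dim. Of 14 basal cell markers measured, 1 was at or above the median level, the integrin gene ITGA6, 1.94-fold lower. Of 21 neuroendocrine markers, 2 were: SYT4, a synaptotagmin, 1.92-fold higher, and ENO2, 1.17-fold higher. Of 20 endothelial and blood cell markers, CD68 alone was, at 1.72-fold higher. Epithelial adhesion genes had a median of 0.18 over 23 genes, 18 of them higher, at the 99.9 percentile. CDH3, which encodes P-cadherin, was 5.19-fold higher, ELF3 1.69-fold, the tight junction gene MARVELD2 1.51-fold and the claudin gene CLDN3 1.38-fold. Of the 7 mesenchymal genes at or above the median level, 4 were lower and 3 higher. Their median was -0.01, and it was 0.03 under quantile normalization and under loess removal. TWIST1, a mesenchymal transcription factor, was 2.15-fold lower, FN1, fibronectin, 1.11-fold, CALD1 1.02-fold and COL1A1 1.01-fold.

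Genes of the NF-kB and inflammation list were higher. Of 7 members at or above the median level, 6 were higher and 3 at least 2-fold: PTGS2, the chemokine genes CCL20 at 3.64-fold and CCL2 at 2.85-fold. SOD2, mitochondrial superoxide dismutase, was 1.53-fold higher and is the median member, and its neighbours on chromosome 6 had a median of 0.32. The median of 0.61 lay above all 10000 random lists. It was 0.088, at the 99.2 percentile, with no level filter and 0.29, at the 99.4 percentile, with the neighbour median removed. It was 0.18, at the 95.6 percentile, without genes on chromosomes 1, 6 and 9, where PTGS2 and SOD2 lie, and 0.18, at the 82.0 percentile, among genes in the upper quartile of level. The list's genes NFKB1, NFKB2 and NFKBIA, named after their values were seen, differed by -0.12, 0.08 and 0.18. The interferon response list would hold a response to foreign nucleic acid, but one shared by both transfected cultures would not show in their difference. Of its 40 measured genes, 10 were at or above the median level, with a median of 0.05 at the 82.5 percentile. Of these genes 5 were higher, among them IFI6 at 1.44-fold, UBE2L6 at 1.34-fold, IFIT5 at 1.28-fold and IRF7 at 1.26-fold, and 5 were lower. The median turned to -0.28 among genes in the upper quartile of level and to -0.17 without chromosomes 1, 6 and 9.

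Cytosolic ribosomal protein genes were slightly lower, with 47 of 56 lower and a median of -0.11 at the 0.41 percentile. RPS23 was 1.66-fold lower, RPS24 1.51-fold, RPL7A 1.44-fold and RPL35 1.29-fold, and the last 2 lie on chromosome 9. Against random lists not matched on level, the same median lay at the 4.22 percentile, and with the neighbour median removed it was -0.058, at the 0.92 percentile. In all, 8 of 26 lists stood apart. By chance alone 1.3 would on average if genes within a list varied independently, which co-regulated genes do not.

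**Figure D2:**
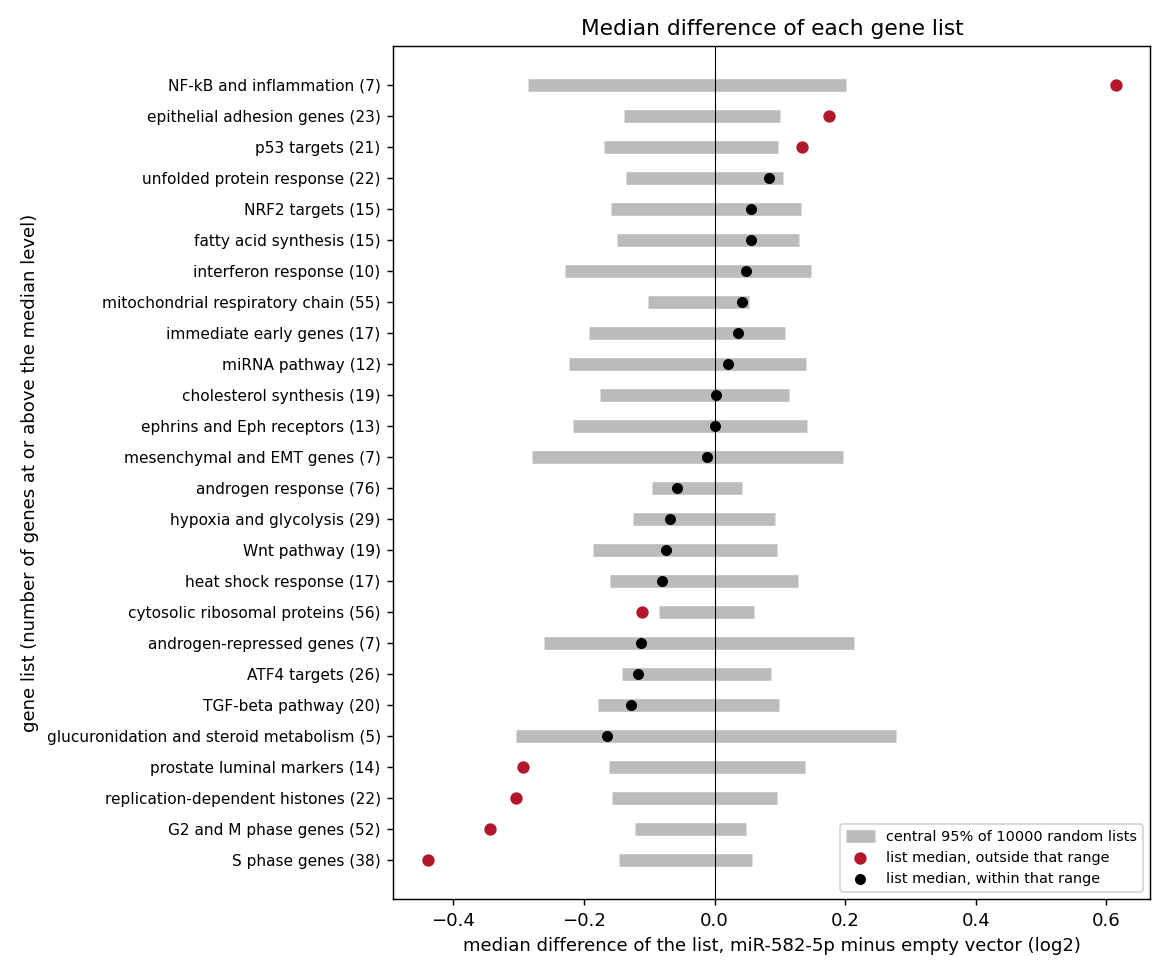
The x axis gives each list's median difference, miR-582-5p minus empty vector (log2), and each row is a gene list with its number of genes at or above the median level. Grey bars show the central 95% of 10000 random lists matched on level; red points lie outside it, from the S phase genes at -0.44 to the NF-kB and inflammation list at 0.61, and black points lie within it.

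Ephrins and Eph receptors went both ways. Of 13 genes, 6 were higher and 6 lower, and the median was 0.00. EFNA1 was 1.74-fold, EPHA6 1.72-fold and EPHA1 1.67-fold higher, against EFNB2, which was the 1 member at least 2-fold apart. With the brightest probe set per gene the median was 0.29, at the 99.9 percentile. The TGF-beta pathway list had a median of -0.13 over 20 genes, at the 10.3 percentile. PMEPA1 was lower, FKBP1A was 1.45-fold and LTBP2 1.39-fold lower, and the matrix gene THBS1 was 2.45-fold higher. The Wnt pathway list had a median of -0.07 over 19 genes, 7 higher and 12 lower. FZD5 was 1.52-fold, TCF7L2 1.30-fold, FZD8 1.28-fold and LRP5 1.22-fold lower. The 12 genes of the miRNA pathway had a median of 0.02, with 6 higher and 6 lower. The largest in the direction of the median were TNRC6B at 1.29-fold, AGO3 at 1.27-fold, AGO4 at 1.23-fold and DICER1 at 1.22-fold higher. AGO3 and AGO4 lie on chromosome 1, whose genes as a group were higher.

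Metabolic and stress lists lay within the range of random lists. Cholesterol synthesis genes had a median of 0.00 over 19 genes, 10 higher and 9 lower. TM7SF2 was higher by 0.59 on the log2 scale, and MSMO1 was 1.24-fold, SC5D 1.16-fold and PMVK 1.10-fold higher. PMVK lies on chromosome 1, where its neighbours had a median of 0.18. Fatty acid synthesis genes had a median of 0.06 over 15 genes, with FASN, fatty acid synthase, 1.48-fold, ACSL1 1.47-fold and SREBF1 1.42-fold higher and ELOVL7 1.85-fold lower. Mitochondrial respiratory chain genes had a median of 0.04 over 55 genes, 30 higher and 25 lower. COX7A2 was 1.59-fold, COX7B 1.36-fold, COX8A 1.29-fold and COX6C 1.23-fold higher. COX7A2 lies on chromosome 6, where its neighbours had a median of 0.26. The unfolded protein response list had a median of 0.08 over 22 genes, 15 higher and 7 lower. HERPUD1 was 1.33-fold, DNAJC3 1.31-fold, EDEM1 1.24-fold and DNAJB9 1.13-fold higher. ATF4 targets had a median of -0.12 over 26 genes. PSAT1, which lies on chromosome 9, was 1.61-fold, SHMT2 1.37-fold and MTHFD2 1.36-fold lower and VEGFA 1.62-fold higher. The neighbours of VEGFA, on chromosome 6, had a median of 0.26. The hypoxia and glycolysis list had a median of -0.07 over 29 genes, with PFKFB3 1.34-fold, HK2 1.32-fold and PFKFB4 1.29-fold lower and ADM, adrenomedullin, 2.57-fold higher.

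The heat shock list had a median of -0.08 over 17 genes. CHORDC1 was 1.55-fold, HSP90AA1 1.49-fold and DNAJA1 1.44-fold lower, and the small heat shock protein gene CRYAB was 3.57-fold higher. DNAJA1 lies on chromosome 9, where its neighbours had a median of -0.38. NRF2 targets had a median of 0.06 over 15 genes, 8 higher and 7 lower. TXNRD1 was 1.71-fold, NQO1 1.58-fold, GCLM 1.22-fold and PRDX1 1.15-fold higher. GCLM lies on chromosome 1, where its neighbours had a median of 0.24. Immediate early genes had a median of 0.04 over 17 genes, with DUSP5 2.04-fold, ZFP36 1.61-fold and JUN 1.47-fold higher and FOS 1.96-fold lower. Of 23 measured genes of the glucuronidation and steroid metabolism list, 5 were at or above the median level. HSD17B6 was 1.36-fold, HSD17B10 1.13-fold and HSD17B4 1.12-fold lower, and the other 2 were higher. The list's median of -0.16 has no settled direction, as it turned to 0.05 under quantile normalization, 0.04 with no level filter and 0.03 with the brightest probe set. It also leaves out the UGT2B genes, as none of the 5 with a probe set of their own reached the median level. All 5 were higher, with a median of 3.02. The 4 probe sets that list several UGT2B genes, outside the gene table, had a median of 3.55.

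Differences also followed chromosomes, a pattern examined after the data were seen. The 380 genes of chromosome 9 had a median difference of -0.34, and all 19 consecutive windows of 20 genes lay below 0, between -0.45 and -0.20. Each of 23 chromosomes was divided at the gene that left the least absolute deviation from the medians on its sides, and chromosomes 6 and 4 are given because their steps were the largest. On chromosome 6 the median was -0.11 over the first 203 genes, up to C6orf132, and 0.36 over the 241 genes from MRPS10 on, where all 12 windows lay above 0. Chromosome 1 had a median of 0.15 over 946 genes, with all 47 windows above 0. On chromosome 4 the median was 0.14 over the first 168 genes and -0.09 over the other 152. The boundary was searched for again in 1000 shuffles of each chromosome's own gene order. The step of 0.47 on chromosome 6 was larger than the highest of them (0.42), and 7 shuffles of chromosome 4 gave a step as large as its own, a count that does not allow for the choice among 23 chromosomes. The medians of chromosomes 1 and 9 lay beyond those of all 10000 random lists, as did the smaller medians of whole chromosomes 4, 5, 6, 11, 13, 17, 20 and X. Named genes in these regions can be set against their surroundings: FUCA2 lies in the higher block of chromosome 6, where the median of its neighbours was 0.41, and was itself at -3.87.

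**Figure D3:**
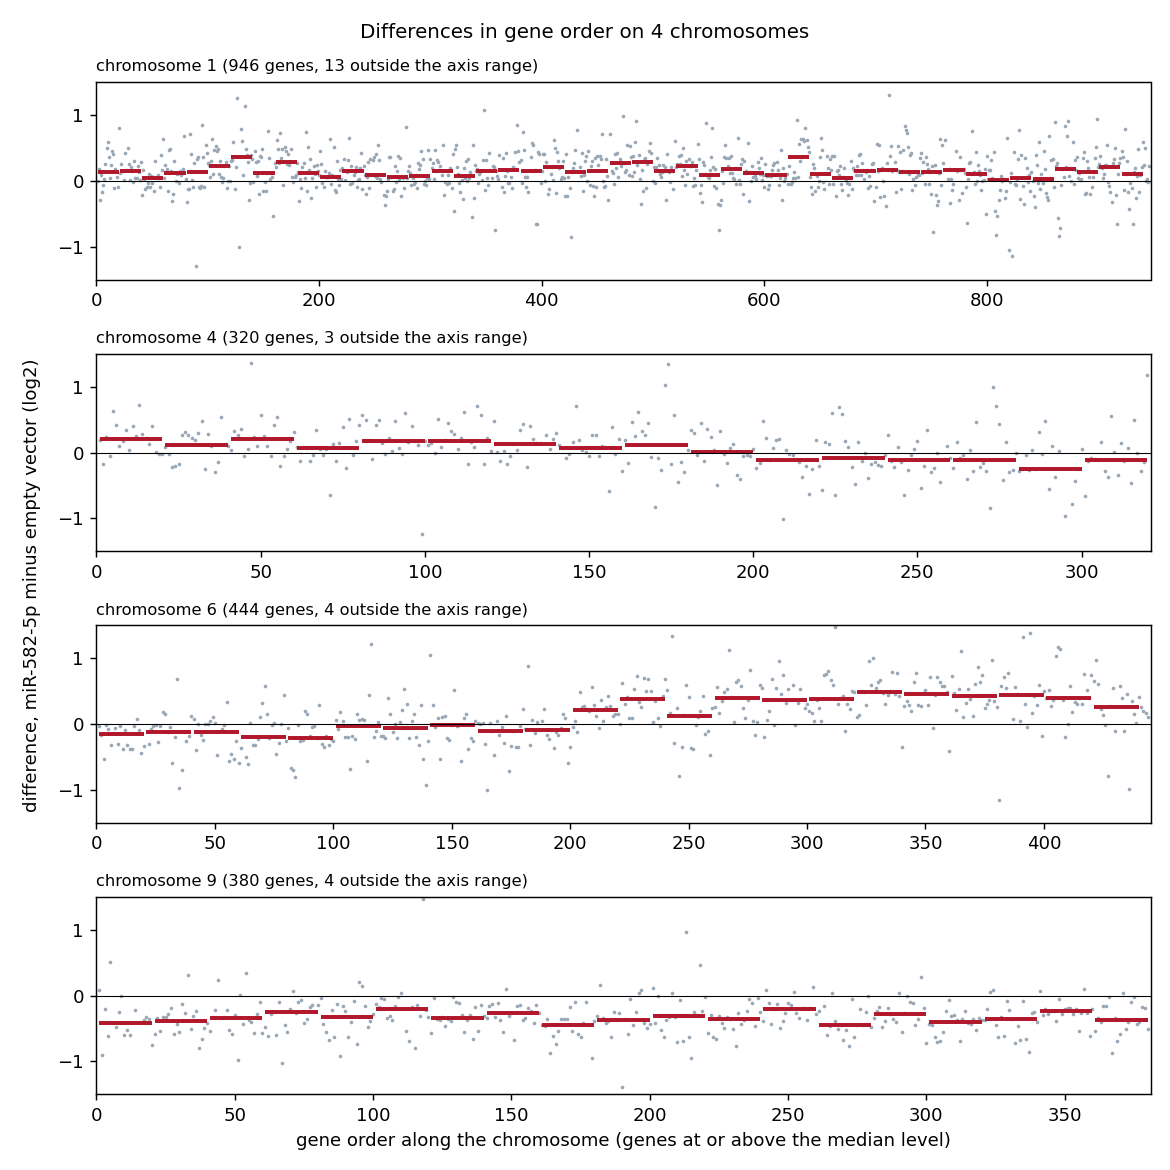
Each grey point is a gene at or above the median level, in its order along chromosomes 1, 4, 6 and 9 on the x axis, with its difference, miR-582-5p minus empty vector, on the y axis (log2, cut at 1.5 in each direction). Red bars are medians of 20 consecutive genes; on chromosome 9 all 19 lie below 0, and on chromosome 6 they lie below 0 up to the step and above 0 beyond it.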

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

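The families below were chosen after their values were seen. Probe sets whose annotation lists several genes were outside the gene table and are given as values only. Of 1752 such probe sets, 31 were at least 2-fold higher and 14 at least 2-fold lower in the miR-582-5p cells. The 4 probe sets that list SSX genes, a cancer-testis family of the X chromosome, had a median difference of 4.04 (9.49 against 5.46), with the highest at 5.47. Their empty vector level is near that array's lower quartile of 5.21 and is not shown to be above background, so the size of the difference is uncertain. The 4 that list UGT2B genes, enzymes that conjugate steroids including androgens, had a median of 3.55, at 13.00 against 9.45. UGT2B17 and UGT2B10, which have probe sets of their own but lie below the median level, and whose empty vector values are also dim, differed by 3.72 and 3.14. Of all 5 UGT2B genes with a probe set of their own, 3 were at least 2-fold higher, and the lowest differed by 0.12. The 4 that list thymosin TMSB4X genes had a median of 2.38, and the 7 that list HLA-DR or HLA-DQ alpha genes had a median of 0.45, with 3 at least 2-fold higher. Lower values were found in the 5 that list XAGE1 genes, at -1.36, the 2 that list MAGED4 genes, at -1.66, and the 5 that list the small nucleolar RNA SNORD3, at -1.03. Probe sets of one family read largely the same transcripts and do not count as independent measurements, and the member that differed was not resolved. Of 7807 probe sets unnamed here, 17 were at least 2-fold higher and 14 at least 2-fold lower.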

How the results depend on the processing

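With 1 array per group, no alternative replaces a second culture, and no replicate could be left out. No paired analysis was possible because each group holds 1 sample. Signal limits dim genes: the counts of genes at least 2-fold higher and lower (89 and 79) were 162 and 165 with no level filter, 30 and 32 at the upper quartile of level, 315 and 344 at 1.5-fold, and 39 and 25 at 3-fold. They stayed within 1.5 times under quantile normalization, loess removal, the brightest probe set, and the 2 settings added after seeing the data. Quantile normalization and loess removal left all 26 lists on their side of the limits. With no level filter, androgen response stood apart at -0.10, NRF2 targets at 0.10, and androgen-repressed genes turned to 0.21. At the upper quartile androgen-repressed genes turned to 0.52, ephrins and Eph receptors stood apart at 0.29, and p53 targets (0.14) and the NF-kB list (0.18) did not. With the brightest probe set, ephrins (0.29) and the respiratory chain (0.055) stood apart. Against unmatched random lists the ribosomal proteins (-0.11) did not. With the neighbour median removed, p53 targets (0.076) did not stand apart and ephrins (0.18) did. Without chromosomes 1, 6 and 9, p53 targets (0.067) and the NF-kB list (0.18) did not, while fatty acid synthesis (0.13), androgen-repressed genes (-0.68) and the respiratory chain (0.038) did, and no histone gene was left. The filters and the left-out chromosomes change which genes are in a list. Quantile normalization, loess removal and the brightest probe set reset the median level, so they can also change which genes are in a list. The cause of each change was not tested. Some medians that stood apart in neither setting turned sign, among them the interferon list and the glucuronidation and steroid metabolism list. All 126 named genes under quantile normalization, loess removal and the brightest probe set, and all 125 that had neighbours at their level, kept their direction or moved by less than 1.5-fold. That says little about their reliability, because these settings barely move single genes. The largest log2 shifts were 0.043 with quantile normalization, 0.046 with loess removal, 0.25 with the brightest probe set and 0.41 with the neighbour median removed. Most named genes have 1 probe set, so choosing the brightest leaves them unchanged. The seed-site comparison was not run, and the offset settings do not apply to log2 values.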

Other observations

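Several large differences came in gene families and neighbours, all named after their values were seen. Of 18 protocadherin beta genes, which form a cluster of cell adhesion genes on chromosome 5, 17 were lower and 7 at least 2-fold lower, with a median of -0.70, though 2 alone were at or above the median level. Among small nuclear RNA genes, 13 of 15 spliceosomal genes were lower and 4 at least 2-fold, but 5 alone were at or above the median level. Of 61 H/ACA box small nucleolar RNA genes, 6 were at least 2-fold lower and none as much higher, with 28 at or above that level. None of the 115 SNORD genes with a probe set of their own, 51 of them at that level, passed 2-fold in either direction. That count leaves out the SNORD3 probe sets that list several genes. With no level filter, 165 of all 18377 genes were at least 2-fold lower and 162 at least 2-fold higher. PEG10 (-3.96) and its neighbour SGCE (-3.47) were lower and MEST (3.56) was higher, but the dimmer value of each, such as 5.71 for SGCE, lay below its array's median of 6.63, so these sizes are uncertain. These 3 genes are known to be imprinted, and imprinted genes as a group were not tested. The 5 measured MAGEA genes had a median of 0.46, and 1 of them, MAGEA4, was at least 2-fold higher. PLA2G4A, which encodes the cytosolic phospholipase that releases arachidonic acid, was higher by 2.70 beside PTGS2, the next gene in order on chromosome 1.

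In the 3 patterns that follow, the tests by windows along a chromosome and by the share of cell cycle genes lower were chosen after the result was seen, as were the removal of the neighbour median and the shuffles of gene order within chromosome 6, whose comparison by length was chosen after the shuffles' shares were seen; the patterns themselves were noticed in these data. The block shifts of chromosomes 9 and 6 do not come from a trend with level: after loess removal the medians were -0.30 and 0.39. Nor do a few strong genes make them, since 89.2% of chromosome 9 genes lay below the median of all genes and 89.6% of the 241 genes of the chromosome 6 block above it, a share that 13 of 1000 shuffles with a boundary chosen the same way reached with at most 31 genes, and that none of the 458 with at least 241 genes reached (highest 74.4%). All windows, 100% in each block, lay on the same side. That alone does not set a block apart: all 15 windows of chromosome 15 lay below 0, with a median of -0.05 at the 15.96 percentile. Dim, middle and bright genes had medians of -0.32, -0.36 and -0.31 on chromosome 9 and 0.34, 0.41 and 0.32 in the chromosome 6 block. A candidate explanation is a different number of copies of these regions in the 2 cell lines: the median ratios of 0.792 and 1.28 may be set beside 0.75 for 3 copies of 4 and 1.25 for 5 of 4. The ratios of chromosome 1 (1.11) and the first part of chromosome 4 (1.10), whose windows also all lay above 0, are near neither. The base of 4 copies is an assumption, and ratios from other copy numbers were not compared. The block ratios were not corrected for the median of all genes, -0.03. No DNA was measured here, and with 1 line per group a difference between lines cannot be separated from the transfection.

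The lower cell cycle genes are not explained by these blocks or by a trend with level. The pooled median of 90 genes of both lists was -0.38, and it was -0.35 with the neighbour median removed and -0.36 after loess removal. Of these genes 87.8% were lower, as were 86.4% of the histone genes. Fewer cycling cells or slower cycling in the miR-582-5p culture when RNA was taken could give such shares. The shares restate the pattern that prompted this explanation, so they do not test it. Culture density, which could do the same, and an effect of the miRNA both stay open.

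Strongly different genes lay side by side more often than their number gives, among them SLITRK3 (2.92) with BCHE (3.21). The order held 18325 genes, with 162 at least 2-fold higher and 165 lower, and no level filter was applied. In it, 19 pairs of adjacent genes were both past 2-fold in the same direction. In 10000 shuffles of the positions the median was 3 and the highest 12. Pairs can overlap, as in the run from SPIC to GNPTAB on chromosome 12, so they are not 19 separate places. Some members were dim and may be background, such as BRINP3 at a mean of 5.73 and SYCP3 at 5.69. Leaving out pairs whose symbols share their first 3 characters, as members of a family that could share probes would, 13 pairs remained against a highest of 10, although ULBP1 and RAET1L are related genes that this rule keeps. Wide shifts along a chromosome do not account for them either, as 16 of the 19 remained with the neighbour median removed. A local change of chromatin or DNA in 1 of the lines may underlie such pairs, a hypothesis that these data do not test.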
